A study of Mus musculus with 32 samples.

How the data were processed

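RNA was measured in multipotent progenitors sorted from mouse bone marrow as 4 subsets, MPP1, MPP2, MPP3 and MPP4. The mice carried no, 1 or 2 copies of the Cxcr4 1013 allele, written here as wild type, +/1013 and 1013/1013. The allele shortens the cytoplasmic tail of the chemokine receptor CXCR4, as in WHIM syndrome. Per the labels, each library came from a pool of 3000 cells, with 350 to 1000 pg of RNA input, SMART-Seq v4 amplification for 12 PCR cycles and Nextera XT library preparation. There were 32 libraries in 12 groups. Each subset had 3 wild-type, 3 +/1013 and 2 1013/1013 libraries, so the genotypes had 12, 12 and 8. The labels do not say that the libraries came from separate animals. The p-values therefore measure the spread between these libraries.

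The values used were the deposited counts, which the file headers call raw, in 32 columns for 30644 Ensembl genes. The submitters' processing notes give STAR for alignment, HTSeq for counting and mm10 as the build, with versions and the strand setting not given in the sources used here. Without the strand setting, overlapping genes on opposite strands cannot be separated. Another 64 per-sample columns, with normalized values and values divided by length, were not used. The deposited median transcript length of each gene, in bases per the file headers, served only for checks of gene length. Of the gene identifiers, 30606 (99.9%) were in GENCODE release M21, and 29371 (96% of those) had the same coordinates.

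Library totals ran from 13016038 counts (MPP2 wild type 3) to 37050983 (MPP4 +/1013 1), with a median of 28500000. No pair of libraries was identical, and Spearman correlations between replicates were 0.833 to 0.917. The median dispersion was 1.23, a coefficient of variation of 1.11 between libraries. The reads carry no molecular identifiers, and the floor used below covers counting error only.

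Counts were fitted with edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group. filterByExpr on the 12 groups left 18676 genes, and 3883 genes had no count in any library. Scaling was TMM, the dispersion was the mean trend from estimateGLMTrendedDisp, and glmQLFit and glmQLFTest gave a quasi-likelihood F-test with 20 residual and 3.24 prior degrees of freedom. Standard errors are the log2 difference divided by the square root of F. P-values were adjusted by the Benjamini-Hochberg method in each comparison, with a threshold of 0.05, and every adjusted p of a gene comes from this test unless another tool is named. The comparisons were each mutant genotype against wild type in each subset, the equal-weight mean of the 4 subset differences, 1013/1013 against +/1013 on the same mean, the effect in MPP4 minus the mean effect in MPP1 to MPP3, and MPP2, MPP3 and MPP4 against MPP1 in wild type. Levels are TMM-scaled CPM (counts scaled to a common library size), given as mean and SD. Where every library of 1 group had no count, the fold is against a floor of 3 counts per library and is written as at least that fold. Fitted log2 values of such genes depend on the prior count and are no bound. Medians of lists were also computed with such genes at their bound.

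The 41 gene lists, covering energy metabolism, translation, stress, cell cycle, signalling, lineages and other cell types, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 tested members. The adjustment was over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were run beside it.

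Groups, comparisons, tests, gene lists and the rule for naming genes were chosen before the data were examined. Per comparison, the rule names Cxcr4. It names the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 1 CPM, with no overlap between the compared groups' libraries (for means over subsets, the same sign in all 4) and with a symbol that is not a predicted model or pseudogene. It names up to 4 passing members of each list. Where fewer than 5 genes pass, it names the 5 of lowest p as values. Markers of subset identity are list members given as values. Genes named outside the rule are marked as chosen after their values were seen.

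The fit was tested on simulated data, with changes of 2-fold, 4-fold and 8-fold planted in 67, 67 and 66 genes. Changes were planted only in genes above a set mean level, so the rates do not cover genes of low level. The simulated libraries differed only by size and by the dispersion trend, without the structure between libraries described below. It recovered 1.49%, 35.8% and 72.7% of them for 1013/1013 against wild type in MPP4, 37.3%, 77.6% and 98.5% for the 1013/1013 mean over subsets, 2.99%, 38.8% and 74.2% for +/1013 in MPP4, 50.7%, 94% and 98.5% for the +/1013 mean, and 4.48%, 41.8% and 80.3% for MPP4 against MPP1. The false calls were 0 of 73, 7 of 149, 5 of 82, 17 of 179 and 4 of 88.

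The alternatives were RLE size factors, no filter, a replicate block, a term for the 5 libraries numbered from 46 on, fits of 1 subset alone, each library left out, DESeq2 1.42.0, and limma-voom with genotype and replicate number as a random block. Chosen after seeing the data were a term for the 8 libraries whose number is a multiple of 3, fits without those 8, fits without the 2 libraries of fewest genes, a term for the 11 libraries under 1 CPM of Ddx3y, and an offset that removes a trend with transcript length. Some single-gene results are not reported here. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.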

Results

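Cxcr4 encodes the chemokine receptor that holds progenitors in the marrow, and it carries the 1013 allele. In wild type it had 21.9 ± 4.77 CPM in MPP1, 29.2 ± 0.586 in MPP2, 27.6 ± 21.9 in MPP3 and 51.6 ± 53.4 in MPP4 (mean ± SD, n = 3 each). The +/1013 libraries had 26.6 ± 0.749, 36.3 ± 9.88, 42.3 ± 36.7 and 66.3 ± 38.4 CPM (n = 3), and the 1013/1013 libraries had 47.6 ± 15.8, 86.1 ± 22.9, 35.3 ± 0.457 and 96.6 ± 51 CPM (n = 2). Over the 4 subsets, the log2 difference of Cxcr4 from wild type was 0.39 (SE 0.34, adjusted p = 1) in +/1013 and 0.99 (SE 0.37, adjusted p = 0.177) in 1013/1013. Between 1013/1013 and +/1013 it was 0.59 (SE 0.37, adjusted p = 0.712). None of these differences passed the threshold. Libraries whose number is a multiple of 3 differed from the others in many genes, as described below, and had a median of 77.2 CPM of Cxcr4 against 29.6 in the rest. Without them, MPP2 and MPP4 each have a lone 1013/1013 library. With a term for those 8 libraries the 1013/1013 difference was 1.12, and without them it was 1.37 with an adjusted p of 0.0108, in a range of 0.0108 to 0.415 over the alternatives of this result.

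Wild-type MPP4 expressed the genes of early lymphoid priming far above MPP1. Dntt, the template-independent polymerase of antigen-receptor joints, had no counts in MPP1 and 3170 ± 1040 CPM in MPP4, at least 23700-fold higher (n = 3 against 3, adjusted p = 0.0157). The recombinase gene Rag2 was at least 475-fold higher (63.6 ± 16 CPM in MPP4, adjusted p = 0.00524), and Ly6d, a marker of lymphoid commitment, at least 563-fold higher (75.4 ± 75 CPM, adjusted p = 0.000423). Flt3, the cytokine receptor used to sort this subset, rose from 18.8 ± 5.39 to 454 ± 113 CPM (log2 4.59, SE 0.89, adjusted p = 0.00872), and the syndecan gene Sdc1 rose from 17.5 to 240 ± 46.9 CPM (log2 3.78, adjusted p = 4.21e-05). Genes of stem and megakaryocytic cells fell: Apoe from 749 ± 112 to 28.3 ± 16.1 CPM (log2 -4.73, SE 0.51, adjusted p = 3.14e-05), the endothelial adhesion gene Esam from 351 ± 60.6 to 15.8 ± 2.77 (log2 -4.47, adjusted p = 0.00116), the granule-docking gene Rab27b (log2 -4.26, adjusted p = 0.000299), and Itga2b, the platelet integrin, from 207 ± 43.1 to 11.4 ± 4.8 (log2 -4.19, adjusted p = 0.0137). In all, 142 genes passed, 84 higher and 58 lower in MPP4. DESeq2 called 777 and limma-voom 465.

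Gene lists gave the same division of MPP4 from MPP1 in wild type. The 41 tested lymphoid priming genes were higher (median log2 difference 3.24, and 3.21 with genes of all-zero groups at their bound, adjusted p = 6.9e-17), with 8 members past the threshold over all genes and 20 higher members adjusted over the list alone. B cell genes (median 7.44, at their bound 5.17, adjusted p = 2.16e-11) and MHC class II and dendritic cell genes (median 2.77, adjusted p = 2.16e-11) were higher too. Megakaryocyte genes (median -2.19, adjusted p = 1.91e-14) and long-term stem cell genes (median -1.83, adjusted p = 4.63e-16) were lower, with 5 and 4 members past the threshold over all genes, and 12 and 13 adjusted over the list alone. These 5 lists also passed with an estimated correlation, at adjusted p from 0.00147 to 0.0425. Granulocyte-monocyte genes had a median of 2.74 (adjusted p = 9.45e-14, adjusted p = 0.113 with an estimated correlation), with 5 members past the threshold over all genes and 13 adjusted over the list alone. That median was 1.03 without the 8 libraries described below, of which MPP4 wild type 3 is 1, with 0.407% of its counts in mature neutrophil genes against 0.00913% and 0.0134% in wild type 1 and 2. The count of 142 genes was 163 with a term for the 8 libraries and 139 without them. It was 93, 73 and 83 without MPP1 wild type 1, 2 and 3, and 84 without MPP4 wild type 2. The calls of Dntt and Flt3 were lost without any 1 of the MPP1 wild-type libraries (log2 4.38 to 4.77 for Flt3), and that of Itga2b without MPP4 wild type 1 or 2 (-4.55 to -3.93).

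MPP3 shared part of this profile. The leukocyte tetraspanin gene Cd53 rose from 63.9 ± 11 CPM in wild-type MPP1 to 866 ± 105 in MPP3 (log2 3.76, SE 0.51, adjusted p = 0.00294, n = 3 against 3), and Ly6d, at 30.4 ± 9.66 CPM, was at least 227-fold higher (adjusted p = 0.00863). The chemokine gene Ccl9 rose from 5.34 ± 2.03 to 164 ± 76.2 CPM (adjusted p = 0.0238). Mpo, the granule enzyme of myeloid progenitors, had 980 ± 807 CPM against 11.1 ± 7.85. In all, 19 genes passed, 18 of them higher. The exception was the platelet integrin gene Itgb3, at 13.4 ± 8.02 CPM in MPP1 and 0.0105 ± 0.0182 in MPP3 (adjusted p = 0.04). DESeq2 called 600 genes and limma-voom 180. Lymphoid priming genes (median 2.42, at their bound 2.33, adjusted p = 6.44e-13) and B cell genes (adjusted p = 2.84e-11) were higher and megakaryocyte genes lower (median -1.83, adjusted p = 9.81e-10), and all 3 passed with an estimated correlation at adjusted p from 0.00592 to 0.00702. Of the lymphoid priming genes, 4 passed over all genes and 19 adjusted over the list alone, and of the megakaryocyte genes 1 and 6. Granulocyte-monocyte genes had a median of 2.58 (adjusted p = 6.61e-17, adjusted p = 0.0775 with an estimated correlation), with 1 member past the threshold over all genes and 13 adjusted over the list alone. It was 2.18 without the 8 libraries, and MPP3 wild type 3, 1 of them, had 0.28% of its counts in mature neutrophil genes against 0.0065% and 0.0127% in the other two. The count of 19 was 25 with a term for the 8 libraries and 22 without them. It was 8, 0 and 3 without MPP1 wild type 1, 2 and 3, and 6 and 4 without MPP3 wild type 2 and 3. The call of Cd53 was lost without MPP1 wild type 2 and that of Ly6d without MPP1 wild type 2 or 3 (log2 of Cd53 3.66 to 3.89). That of Ccl9 was lost without any 1 library but MPP3 wild type 1 (4.57 to 5.28), and that of Itgb3 without any 1 of the 6.

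MPP2 differed from MPP1 by no single gene that passed the threshold. The highest levels of the erythroid regulators Gata1 (244 ± 129 CPM, against 101 ± 17.2 in MPP1) and Klf1 (36.5 ± 29.5 against 9.07) and of the platelet genes Pf4 (137 ± 66.1 against 65.1 ± 26.5) and Gp5 (124 ± 43.1 against 74.2 ± 27.2) among the wild-type subsets were in MPP2. All 41 tested G2/M cell cycle genes were positive (median 0.74, adjusted p = 6.16e-10, adjusted p = 0.302 with an estimated correlation), with 0 past the threshold over all genes. The erythroid list had a median of 1.45, and 1.32 with genes at their bound (adjusted p = 6.8e-05, adjusted p = 0.518 with an estimated correlation). Its median was 0.23 without the 8 libraries. Hemoglobin genes took 0.146% of the counts in MPP2 wild type 3, 1 of the 8, and 0.00308% and 0.00281% in wild type 1 and 2. The megakaryocyte list had a median of only 0.10, and 0.23 without the 8 libraries. Larger medians were in granulocyte-monocyte genes (1.73), basophil, mast cell and eosinophil genes (4.34) and B cell genes (4.59). Without the 8 libraries these were 0.88, 3.12 and 0.04. Camera called 21 of the 41 lists, 19 higher and 2 lower. EdgeR called 0 genes, with a lowest adjusted p of 0.0609 and 785 genes at an unadjusted p under 0.05. DESeq2 called 271 and limma-voom 6. Without MPP2 wild type 1 and 2, 1 and 2 genes passed.

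**Figure D1:**
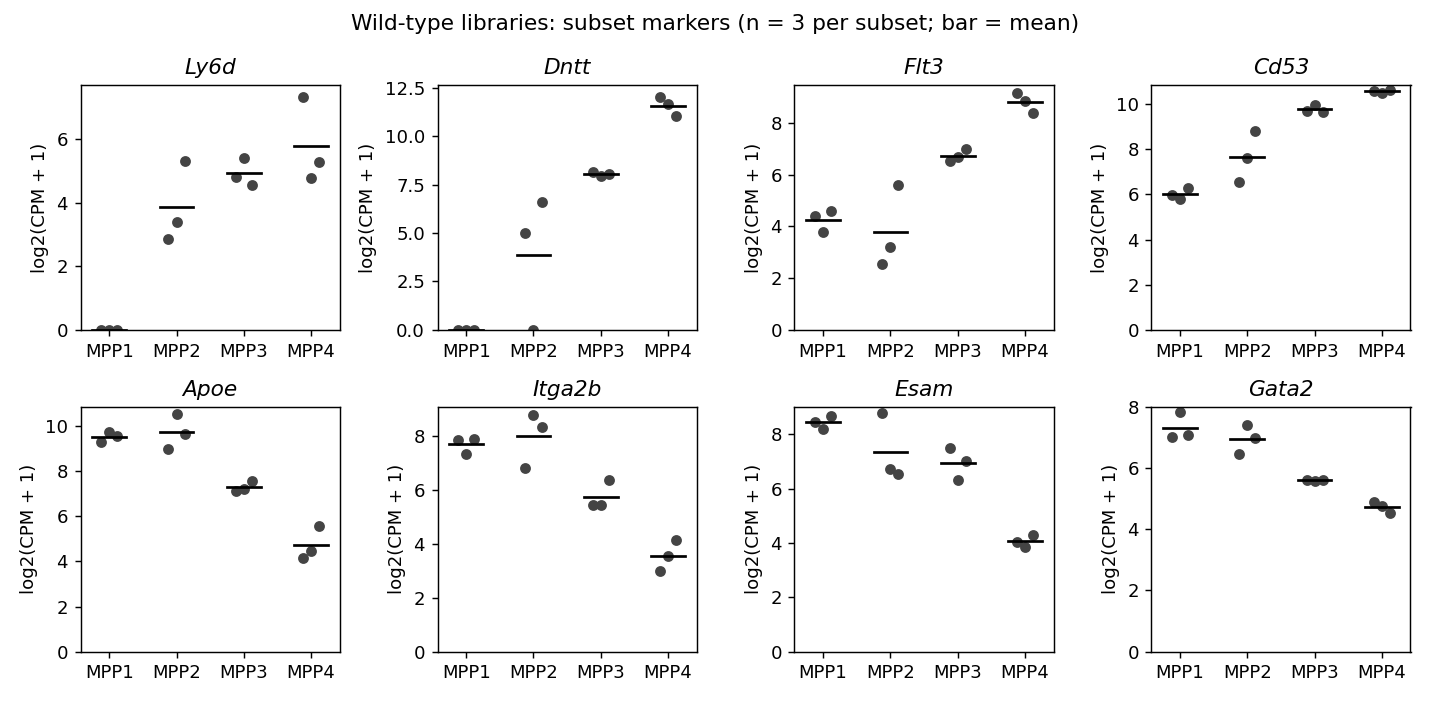
Levels of 8 subset markers in wild-type MPP1 to MPP4 as log2(CPM + 1), 1 point per library, with the mean as a bar (n = 3 per subset).

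The 8 libraries with a number that is a multiple of 3 differed from the rest in genes chosen after their values were seen. Fos, an immediate-early gene that responds within minutes to handling, had 64.6 to 949 CPM in them and 1380 to 9320 in the other 24. Egr1, of the same class, had 9.76 to 152 against 58.3 to 2280 CPM. S100a8, an abundant neutrophil transcript, had 15.1 to 763 CPM against 0 to 28.6, and mature neutrophil genes took 0.00797% to 0.527% of the counts against 0.00432% to 0.0134%. Of the 8, MPP4 1013/1013 2 lay within the range of the rest for S100a8, neutrophil genes and Egr1 (134 CPM), but not for Fos (150 CPM). Hemoglobin genes took a mean of 0.145% against 0.0084%. Mitochondrially encoded genes took a median of 1.52% against 0.808%. The 8 were the third wild-type and +/1013 libraries of MPP2, MPP3 and MPP4 and the second 1013/1013 libraries of MPP2 and MPP4, so MPP1 and 1013/1013 MPP3 had none. The fewest genes with at least 5 counts were in MPP2 +/1013 3 (11612) and MPP4 1013/1013 2 (11693), and the most in MPP4 +/1013 2 (15136). After thinning every library to the smallest total, the MPP4 1013/1013 libraries kept 12612 and 10986 genes and the MPP1 1013/1013 libraries 13784 and 14007.

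**Figure D2:**
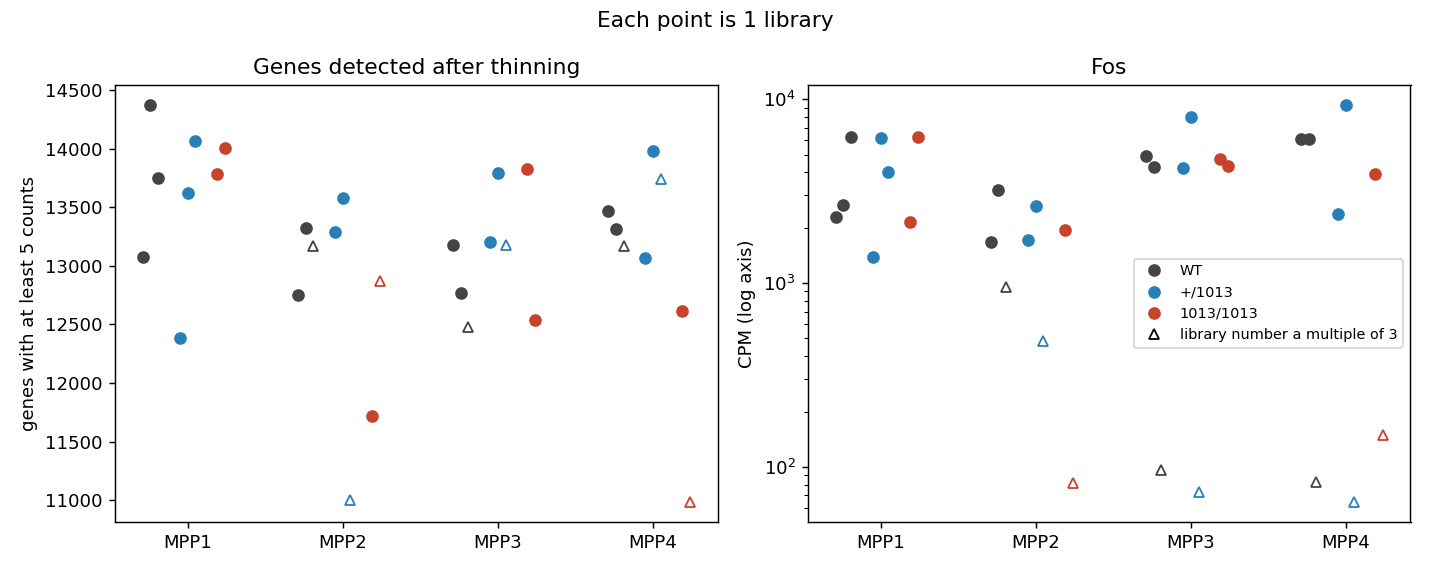
Left, genes with at least 5 counts in each library after thinning to the smallest library; right, CPM of Fos on a log axis. Open triangles are the 8 libraries with a number that is a multiple of 3.

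Ctse, which encodes the aspartic protease cathepsin E, was higher in +/1013 than in wild type. Over all subsets Ctse had 31.2 ± 22.6 CPM in wild type (6.77 to 79.4, n = 12) and 232 ± 88.4 in +/1013 (110 to 412, n = 12), so the libraries of these genotypes did not overlap. The mean log2 difference was 2.97 (SE 0.38, 7.83-fold, adjusted p = 0.000496). The 3 other genes that passed were all higher and all pseudogenes, whose reads may be shared with close copies. Gm5874 on chromosome 6 had 0.796 ± 0.0309 CPM in wild-type MPP1 and 5.13 ± 0.404 in +/1013 (mean log2 difference 2.21, SE 0.26, adjusted p = 0.00025). Gm18666 and Gm7889 on chromosome 1 had no counts in any wild-type library (adjusted p = 0.00186 and 0.00291). In +/1013 MPP4 they were at least 5.29-fold and 3.57-fold higher. They start 34.7 and 34.6 Mb before Cxcr4, and Ctse lies 3.05 Mb from it. Only Gm5874 is thus outside the window of 50 Mb around Cxcr4 described below. These 4 calls held in each of the 24 fits that left out 1 library, and the fits with a term for the 8 libraries and without them called 4 and 5 genes. At an unadjusted p under 0.05 there were 747 genes, DESeq2 called 202 and limma-voom 6.

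Within single subsets no gene passed the threshold in +/1013. Ctse had 16.6 ± 8.55 against 248 ± 34.1 CPM in MPP1 (log2 3.90, SE 0.79, adjusted p = 0.483), 37.3 ± 23.6 against 245 ± 149 in MPP2, 38.7 ± 35.3 against 215 ± 93.2 in MPP3 and 32 ± 21.8 against 221 ± 98.1 in MPP4 (n = 3 against 3). Among the lowest p in MPP2 were those of Gm5874, Srgap3, Slc30a4 and Prkacb (adjusted p = 0.811), in MPP3 those of Itgb3, Atg2b, Atrx, Tctn1 and Gm18666 (adjusted p = 1), and in MPP4 those of Gm18666, Gm5874, Gm7889, Rgs7bp and Ctse (adjusted p = 1). Dntt had 3170 ± 1040 CPM in wild-type and 3410 ± 1090 in +/1013 MPP4, and Flt3 had 454 ± 113 and 424 ± 179. EdgeR called 0 genes in each of the 4 subsets, with 280, 899, 624 and 388 genes at an unadjusted p under 0.05 in MPP1 to MPP4. DESeq2 called 117, 206, 198 and 117, and limma-voom 2, 1, 16 and 12. Without MPP2 +/1013 1, or without MPP3 wild type 1, 1 gene passed in that subset.

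Over the subsets, ribosomal and respiratory-chain genes were called slightly higher in +/1013 at the preset correlation. Of 85 cytosolic ribosome genes 83 were positive (median 0.23, at their bound 0.22, adjusted p = 6.87e-14, adjusted p = 0.659 with an estimated correlation), of 77 mitochondrial ribosome genes 68 (median 0.15, adjusted p = 2.08e-08, adjusted p = 0.659 with an estimated correlation) and of 77 nuclear-encoded respiratory-chain genes 70 (median 0.19, adjusted p = 3.39e-09, adjusted p = 0.666 with an estimated correlation). None of these members passed over all genes. Of 12 plasma cell genes 11 were positive (median 1.43, at their bound 0.97, adjusted p = 6.23e-05, adjusted p = 0.138 with an estimated correlation), 3 of them adjusted over the list alone and 0 over all genes, and this list also passed with fry (adjusted p = 0.0223). The heat shock list was lower (median -0.19, 16 of 17 negative, adjusted p = 0.00676, adjusted p = 0.659 with an estimated correlation), as were mTORC1-induced genes (median -0.05, adjusted p = 0.00494, adjusted p = 0.659 with an estimated correlation). Lymphoid priming genes had a median of -0.04 and a mean of 0.12 (adjusted p = 0.932), with 1 higher and 2 lower members adjusted over the list alone. Camera called 8 lists in all, 5 higher and 3 lower. It called 13 with a term for the 8 libraries and 15 without them, 5 without MPP2 wild type 2, 14 without MPP2 +/1013 2, and 13 without MPP1 +/1013 3, MPP3 +/1013 2, MPP4 wild type 3 or MPP4 +/1013 2.

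In 1013/1013 Ctse was higher as well. The 1013/1013 libraries had 814 ± 154 CPM in MPP1, 264 ± 192 in MPP2, 510 ± 331 in MPP3 and 157 ± 75.8 in MPP4 (n = 2 each), a mean log2 difference of 3.61 from wild type (SE 0.41, 12.2-fold, adjusted p = 5.47e-05). The mitochondrially encoded oxidase subunit gene mt-Co1 rose from 5090 ± 2600 CPM (n = 12) to 11300 ± 4190 (n = 8; log2 1.16, SE 0.22, adjusted p = 0.0129). All mitochondrially encoded genes together took a mean of 0.844% of the counts in wild type, 0.96% in +/1013 and 1.43% in 1013/1013, and mean numbers of genes after thinning to the smallest total were 13300 and 11800 in wild-type and 1013/1013 MPP4 and 13100 and 12300 in MPP2. The p53 target Ccng1 fell (log2 -0.80, SE 0.13, adjusted p = 0.00339), as did the purine synthesis gene Gart (log2 -0.60, SE 0.11, adjusted p = 0.00653). The cation channel gene Trpc6 fell from 138 ± 38.5, 76.5 ± 35.2, 46.5 ± 48.4 and 25.5 ± 16 CPM in wild-type MPP1 to MPP4 to 123 ± 16.2, 58.1 ± 18, 13.6 ± 9.11 and 0.166 ± 0.235 (adjusted p = 0.00538). Rab27b fell from 48.5 ± 24.7 to 22.8 ± 21.6 CPM in MPP2, from 12.6 ± 6.5 to 7.17 ± 0.172 in MPP3 and from 2.43 ± 1.06 to 0 in MPP4 (adjusted p = 0.000492). The imprinted adaptor gene Grb10, which restrains growth-factor signalling, had 17.9 ± 5.27 and 14.5 ± 9.96 CPM in wild-type MPP2 and MPP3 and 4.72 ± 4.73 and 0 in 1013/1013 (adjusted p = 0.0222). The B cell and progenitor marker Cd24a rose slightly (log2 0.62, SE 0.14, adjusted p = 0.0422).

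Over the subsets, 128 genes differed between 1013/1013 and wild type, 39 higher and 89 lower, with 3057 at an unadjusted p under 0.05. The median of all genes was -0.166, so these changes are relative to a slightly lower median. DESeq2 called 1896 genes, including all 128, and limma-voom 108, of which 76 were shared. With a term for the 8 libraries 207 genes passed, 127 of them shared, and without those libraries 1187, 115 of them shared. In the fit without the 8 libraries, MPP2 and MPP4 each had a lone 1013/1013 library. A replicate block gave 96, 80 of them shared, and a term for the 5 libraries numbered from 46 on gave 85, 76 of them shared. Another term, for the 11 libraries under 1 CPM of the Y-linked gene Ddx3y (8 of the 12 wild-type and 0 of the 8 1013/1013 libraries among them), gave 138 genes, 64 of them shared. The count was 84 and 83 without MPP1 wild type 2 and 3, 39 and 53 without MPP1 1013/1013 1 and 2, 44 and 1493 without MPP2 1013/1013 1 and 2, 506 and 37 without MPP3 1013/1013 1 and 2, and 749 and 74 without MPP4 1013/1013 1 and 2. The calls of Ctse, Ccng1, Trpc6 and Rab27b held in all 20 of these fits. Those of mt-Co1 (log2 1.06 to 1.33) and Gart (-0.72 to -0.52) were lost in 2 and 1 of them, both without MPP3 1013/1013 2, and that of mt-Co1 also without MPP2 1013/1013 1. The call of Grb10 was lost in 5 and that of Cd24a in 16.

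Genes on chromosome 1 around Cxcr4 were frequent among those 128. The following were chosen after their values were seen. Dars, which encodes aspartyl-tRNA synthetase and starts 0.224 Mb before Cxcr4, fell from 984 ± 145 CPM in wild type (n = 12) to 796 ± 110 in +/1013 (n = 12; log2 -0.30, below the threshold) and 579 ± 124 in 1013/1013 (n = 8; log2 -0.77, SE 0.10, adjusted p = 0.000381). The kinase gene Stk25 had 178 ± 10.4, 110 ± 69.5 and 72 ± 10.4 CPM in MPP1 and 141 ± 22.7, 73.6 ± 36 and 36.2 ± 5.93 in MPP4 of wild type, +/1013 and 1013/1013 (log2 -1.82, SE 0.28, adjusted p = 0.00188 for 1013/1013). Pam, which encodes a peptide-amidating enzyme, had 7.88 ± 1.72, 36 ± 9.86 and 85.9 ± 16.9 CPM in MPP1 (log2 2.84, SE 0.65, adjusted p = 0.0387), a call that 14 of the 20 fits without 1 library lost (log2 2.54 to 3.63). Ctse lies 3.05 Mb from Cxcr4. Within 50 Mb on either side of Cxcr4 lay 13 of the 128 genes, 9 higher and 4 lower, which is 10.2%, against 3.6% of all tested genes (673 genes; odds ratio 3.06, Fisher's exact test, p = 0.000728).

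**Figure D3:**
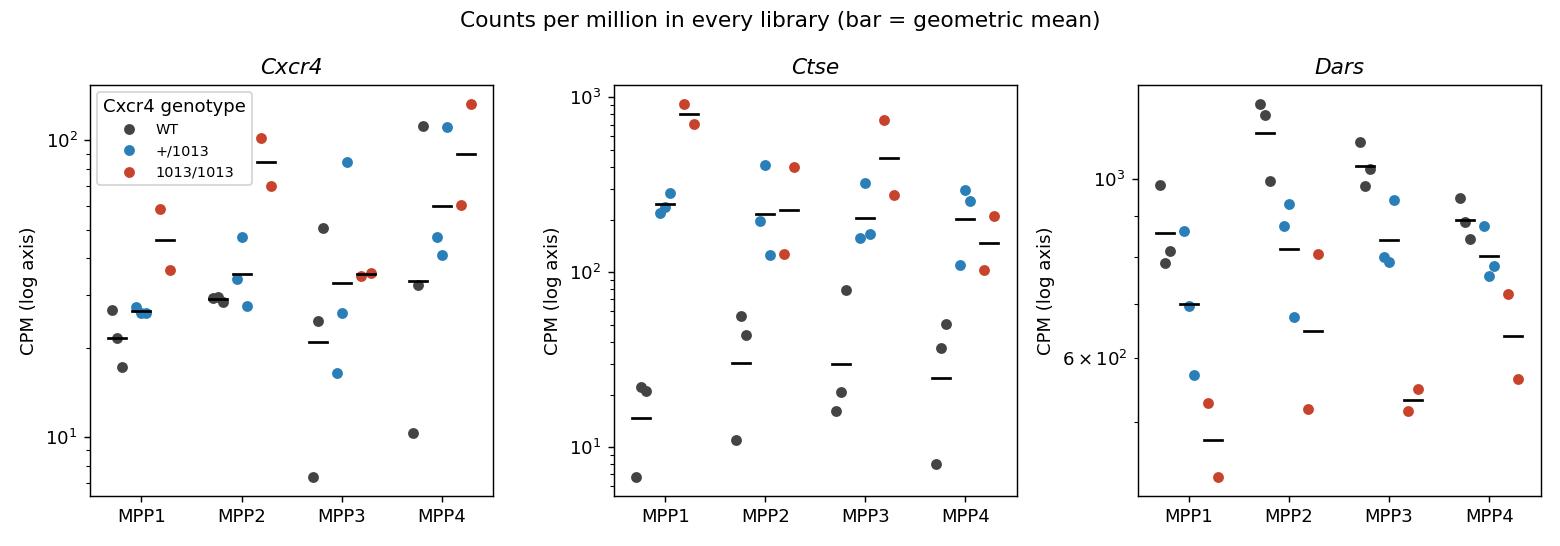
CPM of Cxcr4, Ctse and Dars in every library on log axes, by subset and genotype, with the geometric mean as a bar (n = 3 wild type, 3 +/1013 and 2 1013/1013 per subset).

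Ribosomal and respiratory-chain lists were called higher in 1013/1013 over the subsets and 5 other lists lower, none of them with an estimated correlation. In MPP1 alone, the mitochondrial ribosome and nuclear-encoded respiratory-chain lists were called lower, as given below. Cytosolic ribosome genes were higher (81 of 85 positive, median 0.41, adjusted p = 1.88e-21), with 0 past the threshold over all genes and 17 adjusted over the list alone, as were mitochondrial ribosome genes (71 of 77, median 0.29, adjusted p = 3.02e-15; 0 and 3) and nuclear-encoded respiratory-chain genes (70 of 77, median 0.33, adjusted p = 3.68e-14; 3 higher and 2 lower adjusted over the list alone). In the last list Ndufs1, a subunit of complex I, was the 1 member past the threshold over all genes and it fell (log2 -0.63, SE 0.14, adjusted p = 0.0285). Mitochondrially encoded respiratory-chain genes were higher (8 of 10, median 0.36, adjusted p = 0.00163; mt-Co1 alone passed either way). The 5 lists called lower were ribosome biogenesis and Myc targets (35 of 40 negative, median -0.42, adjusted p = 0.00104), pentose phosphate and nucleotide synthesis (22 of 28, median -0.25, adjusted p = 0.00785; Gart passed over all genes and 5 adjusted over the list alone), glycolysis (20 of 24, median -0.28, adjusted p = 0.018; 0 and 3), mTORC1-induced genes (39 of 50, median -0.27, adjusted p = 0.0199; 1 and 3) and the integrated stress response (22 of 30, median -0.33, adjusted p = 0.0335; 1 and 2). MHC class II and dendritic cell genes were called higher (adjusted p = 0.0133) with a median of 0.22, at their bound 0.26, and a mean of -0.28. For each of these 10 lists the adjusted p was 0.593 with an estimated correlation, so none held. Fry called 4 lists.

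Lineage lists stayed below the threshold in 1013/1013 over the subsets. Lymphoid priming genes had a median of -0.66 (at their bound -0.51, 31 of 41 negative, adjusted p = 0.615), granulocyte-monocyte genes -0.56 (at their bound -0.52, adjusted p = 0.311), erythroid genes -1.21 (at their bound -1.03, adjusted p = 0.361), megakaryocyte genes -0.42 (at their bound -0.29, adjusted p = 0.361; Rab27b past the threshold over all genes and 4 adjusted over the list alone) and long-term stem cell genes -0.31 (at their bound -0.25, adjusted p = 0.197; Trpc6 past the threshold). The p53 and apoptosis list had a median of -0.14 (adjusted p = 0.184), with 2 members past the threshold. mTOR pathway components had a median of -0.16 (adjusted p = 0.441), with 1 higher and 5 lower adjusted over the list alone. The 10 called lists were 11 with a term for the 8 libraries, 14 without them and 6 without MPP3 1013/1013 1.

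**Figure D4:**
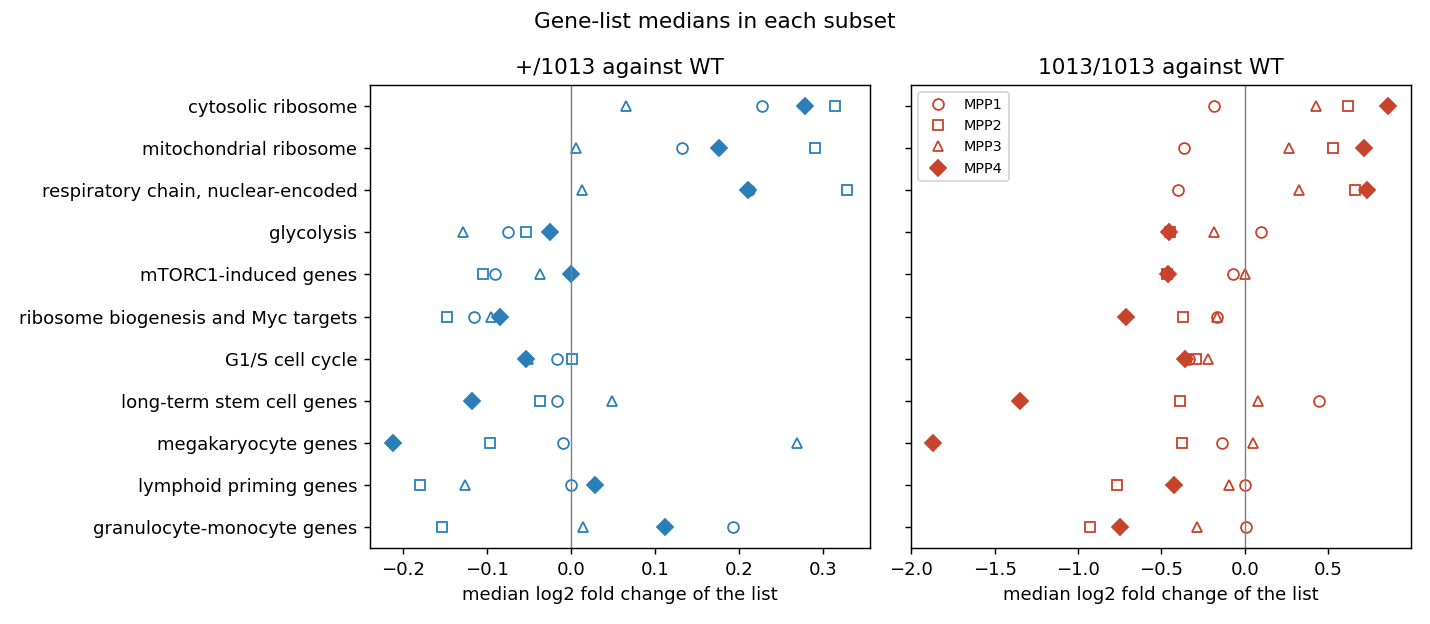
Fitted median log2 difference from wild type of 11 gene lists in each subset, for +/1013 (left) and 1013/1013 (right). The panels have different horizontal scales.

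In 1013/1013 MPP1, Ctse was the 1 gene that passed, at 16.6 ± 8.55 CPM in wild type and 814 ± 154 in 1013/1013 (log2 5.61, SE 0.88, 49-fold, adjusted p = 0.0278, n = 2 against 3). Without any 1 of the 5 libraries of this comparison the call was lost (log2 5.24 to 5.88), as it was without the 8 libraries. In MPP2 the Ras-family gene Mras was the 1 gene that passed, at 3.85 ± 2.46 CPM in wild type and 0 in 1013/1013, at least 35.4-fold lower (adjusted p = 0.0171). The next were Fastkd3, a regulator of mitochondrial RNA (24 ± 3.94 against 101 ± 4.94 CPM, adjusted p = 0.0511), and the pseudogenes Gm5874 and Snrpert (adjusted p = 0.0572 and 0.0615). Mras was not called without MPP2 1013/1013 1. Fits without MPP2 1013/1013 2, which is 1 of the 8 libraries, or without all 8, leave MPP2 1013/1013 1 alone in its group. Their counts of genes in MPP2 rest on that lone library, which had 12511 genes with at least 5 counts. In MPP3, no gene passed. The chromatin remodeller gene Atrx had 2.56 ± 1.63 against 24.7 ± 1.57 CPM, Dars 1040 ± 66.9 against 532 ± 23.6 and Ctse 38.7 ± 35.3 against 510 ± 331, each with an adjusted p of 0.814. Without MPP3 wild type 1 and 1013/1013 1, 1 and 13 genes passed in MPP3. At an unadjusted p under 0.05 there were 384, 2151 and 778 genes in MPP1, MPP2 and MPP3. DESeq2 called 116, 1159 and 277 in these subsets, and limma-voom 29, 40 and 23.

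Ribosomal and respiratory-chain genes were called in opposite directions in 1013/1013 MPP1 and MPP2. In MPP1, mitochondrial ribosome genes had a median of -0.36 (adjusted p = 5.11e-12, adjusted p = 0.439 with an estimated correlation) and nuclear-encoded respiratory-chain genes -0.40 (adjusted p = 1.55e-09, adjusted p = 0.739 with an estimated correlation). NF-kB response genes were higher there (median 0.64, adjusted p = 0.00128), as were long-term stem cell genes (median 0.45, adjusted p = 0.0344), and G1/S genes were lower (median -0.34, adjusted p = 0.000102). No list passed in MPP1 with an estimated correlation, the lowest being adjusted p = 0.197. In MPP2, cytosolic ribosome genes had a median of 0.62 (adjusted p = 2.22e-17) and nuclear-encoded respiratory-chain genes 0.66 (adjusted p = 2.22e-17), and immediate-early genes -1.63 (adjusted p = 5.63e-05). For each of these 3 it was adjusted p = 0.69 with an estimated correlation, and MPP2 1013/1013 2 is among the libraries with low Fos. In MPP3 the same 3 translation and respiration lists were higher, by 0.26 to 0.43 (adjusted p = 0.000151 to 0.024, and adjusted p = 0.99 with an estimated correlation).

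In 1013/1013 MPP4, the adhesion gene Icam2 rose from 129 ± 17.9 to 265 ± 42.8 CPM (log2 1.04, SE 0.23, adjusted p = 0.0315, n = 2 against 3) and Skp1a, a subunit of an ubiquitin ligase, from 1240 ± 56 to 3000 ± 843 (log2 1.28, SE 0.25, adjusted p = 0.0186). The beta-1 integrin gene Itgb1 fell from 264 ± 67.1 to 63.4 ± 20.2 CPM (log2 -2.06, SE 0.44, adjusted p = 0.0294) and the asparaginyl-tRNA synthetase gene Nars from 262 ± 37.9 to 88.5 ± 17.5 (log2 -1.57, SE 0.34, adjusted p = 0.0304). Several genes had no counts in either 1013/1013 library: the nuclear receptor gene Nr2c1 (22.1 ± 5.86 CPM in wild type, at least 158-fold lower, adjusted p = 6.01e-06), the spindle-orientation gene Gpsm2 (15.4 ± 5.94, at least 110-fold, adjusted p = 0.000183), the adhesion receptor gene Adgra3 (17.3 ± 10.1, at least 124-fold, adjusted p = 0.00185) and Rab27b (2.43 ± 1.06, at least 17.4-fold, adjusted p = 0.000137). Trpc6 had 25.5 ± 16 against 0.166 ± 0.235 CPM (adjusted p = 0.00141). The lymphoid genes of MPP4 were not called: Dntt had 3170 ± 1040 CPM in wild type and 3140 ± 80.7 in 1013/1013, Flt3 454 ± 113 and 356 ± 247, Rag2 63.6 ± 16 and 125 ± 7.15, Ly6d 75.4 ± 75 and 687 ± 133, and the chromatin organizer gene Satb1 141 ± 22.5 and 50.6 ± 14.2. Mpo had 513 ± 470 and 135 ± 21.9.

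In all, 133 genes passed in 1013/1013 MPP4, 13 higher and 120 lower, with 2944 at an unadjusted p under 0.05. This was the most of the 4 subsets with all libraries in the fit. Without the 8 libraries MPP2 had more, but MPP2 and MPP4 then each have a lone 1013/1013 library. DESeq2 called 2110, including all 133, and limma-voom 373, of which 95 were shared. With a term for the 8 libraries 183 passed, 132 of them shared, and without those libraries, which leaves 1 1013/1013 library, 64 passed and 27 were shared. A fit of the MPP4 libraries alone, which has fewer samples, called 0. Without the 2 libraries of fewest genes 40 passed, 23 of them shared, with a term for the 5 libraries numbered from 46 on 76, and with the Ddx3y term 89, of which 79 were shared. The count was 55, 82 and 69 without wild type 1, 2 and 3, 752 without 1013/1013 1, and 18 without 1013/1013 2, the library with 11693 genes. A lone library is assumed in these fits to vary like the other groups. Nr2c1, Gpsm2 and Rab27b were called in all 5 of these fits. Without 1013/1013 2 the calls of Adgra3, Trpc6, Icam2, Skp1a, Itgb1 and Nars were lost, the last 4 also without wild type 1, and those of Icam2, Skp1a and Nars also without wild type 3. Their log2 ranges over the 5 fits were 0.88 to 1.18 for Icam2, 0.98 to 1.53 for Skp1a, -2.44 to -1.75 for Itgb1 and -1.80 to -1.36 for Nars.

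As groups, ribosomal and respiratory-chain genes were called higher in 1013/1013 MPP4 at the preset correlation, but not with an estimated one. Over subsets, other splits of the 1013/1013 and wild-type libraries called up to 22 lists at that preset. Lists of single subsets were not tested by splits. The medians were 0.86 for cytosolic ribosome (83 of 85 positive, adjusted p = 1.19e-21), 0.71 for mitochondrial ribosome (76 of 77, adjusted p = 2.98e-24, with 29 adjusted over the list alone) and 0.73 for nuclear-encoded respiratory-chain genes (74 of 77, adjusted p = 1.17e-19). Long-term stem cell genes were lower (median -1.35, at their bound -1.22, adjusted p = 0.00207, with 2 past the threshold over all genes and 8 adjusted over the list alone), as were chemokine receptor signalling and migration genes (median -0.995, adjusted p = 0.0424, with 1 and 1). For each of these 5 lists it was adjusted p = 0.843 with an estimated correlation. Megakaryocyte genes had a median of -1.87 (at their bound -1.42, adjusted p = 0.0519), with 2 members past the threshold over all genes and 5 adjusted over the list alone. mTOR pathway components were not called (adjusted p = 0.404), and 5 fell adjusted over the list alone. Mtor itself had 7.31 ± 2.28 CPM in wild type and 9.73 ± 10.4 in 1013/1013.

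Between 1013/1013 and +/1013 over the subsets, Rab27b was lower in 1013/1013, at 22.8 ± 21.6 against 38.4 ± 4.46 CPM in MPP2 and 0 against 2.39 ± 0.514 in MPP4 (adjusted p = 0.00814). The peptidase gene Dpp8 had 9.13 ± 4.87 against 20.5 ± 12.6 CPM in MPP2, 8.09 ± 0.244 against 38.9 ± 15.1 in MPP3 and 0.907 ± 1.07 against 30.5 ± 15.7 in MPP4 (mean log2 -2.26, SE 0.37, adjusted p = 0.0122). Trpc6 was lower too (log2 -2.22, SE 0.42, adjusted p = 0.0494). Ribosomal lists were higher in 1013/1013 than in +/1013, cytosolic by a median of 0.18 (adjusted p = 4.49e-10) and mitochondrial by 0.14 (adjusted p = 2.36e-08), with adjusted p = 0.968 with an estimated correlation for both. In all, 8 genes passed, all lower, with 1701 at an unadjusted p under 0.05. DESeq2 called 784 and limma-voom 6. Without the 8 libraries, MPP2 and MPP4 each have a lone 1013/1013 library. With a term for the 8 libraries 9 passed, and without them 648. The count was 4 without MPP1 1013/1013 1 or 2 or MPP3 1013/1013 2, 5 without MPP2 1013/1013 1, 26 without MPP2 +/1013 3, 545 without MPP2 1013/1013 2, 43 without MPP3 1013/1013 1 and 343 without MPP4 1013/1013 1. The call of Dpp8 was lost in 3 of these fits (without MPP1 1013/1013 1 or 2 or MPP3 1013/1013 2) and that of Trpc6 in 16 of 20, while that of Rab27b held.

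The 1013/1013 effect in MPP4 differed from the mean effect in MPP1 to MPP3 for 19 genes, all lower in MPP4. Nr2c1 had 20.7 ± 5.34 and 20.5 ± 4.29 CPM in wild-type and 1013/1013 MPP1, 14 ± 4.16 and 15.5 ± 2.29 in MPP2 and 19.3 ± 7.52 and 8.12 ± 3.03 in MPP3, against 22.1 ± 5.86 and 0 in MPP4 (adjusted p = 1.55e-05). Rcor3, a subunit of a repressor complex, had 11.8 ± 6.99 and 19.7 ± 0.116 CPM in MPP3 and 10.9 ± 4.19 and 0.0188 ± 0.0266 in MPP4 (adjusted p = 3.83e-05). Mamdc2 had 60.3 ± 18.3 and 80.1 ± 3.18 CPM in MPP1 and 11.4 ± 6.17 and 0 in MPP4 (adjusted p = 0.00603). Gpsm2 and Rab27b (adjusted p = 0.000937 for both) and Trpc6 (adjusted p = 0.0104) were also among them. Long-term stem cell genes as a list were lower (33 of 40 negative, median -1.11, adjusted p = 2.42e-06, adjusted p = 0.887 with an estimated correlation), with 1 past the threshold over all genes and 4 adjusted over the list alone. At an unadjusted p under 0.05 there were 1536 genes, DESeq2 called 872 and limma-voom 57. With a term for the 8 libraries 18 genes passed, and without them 33. The count was 52 without MPP2 1013/1013 1, 30 without MPP3 1013/1013 2, 453 without MPP4 1013/1013 1 and 9 without MPP4 1013/1013 2, and without the last of these the calls of Mamdc2, Gpsm2, Rab27b and Trpc6 were lost, while those of Nr2c1 and Rcor3 held in all 20 fits.

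For +/1013, the same test called no gene. The lowest p belonged to Gm26616, Rgs7bp, A830005F24Rik, Aspa and Cavin2 (adjusted p = 1), and the Cxcr4 effect in MPP4 minus that in the other subsets was -0.04 (SE 0.77, adjusted p = 1), against -0.11 (SE 0.87, adjusted p = 1) for 1013/1013. EdgeR called 0 genes, with 319 at an unadjusted p under 0.05. DESeq2 called 121 and limma-voom 8. Camera called 0 lists.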

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

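Of the tests in this part, the length-offset fit, the odds ratio of genes at 0 and the relation without the 8 libraries numbered in multiples of 3 were chosen only after the data had been seen; the others were fixed before their results were seen.

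The 1013/1013 effect differed between MPP4 and the mean of MPP1 to MPP3 for 19 genes, which drew attention because the test of that difference itself passed. The fitted log2 values were -11.87 for Nr2c1, -8.42 for Rcor3, -8.32 for Rab27b, -10.96 for Gpsm2, -6.63 for Trpc6 and -11.18 for Mamdc2. They depend on the prior count, since the MPP4 1013/1013 libraries had few or no counts of these genes, and are no bound. Among gene lists, nuclear-encoded respiratory-chain genes (median 0.54), mitochondrial ribosome genes (0.58) and cytosolic ribosome genes (0.58) were higher in this comparison, and long-term stem cell genes (-1.11), megakaryocyte genes (-2.06, at their bound -1.46, adjusted p = 0.0131) and chemokine receptor signalling and migration genes (-0.74, adjusted p = 0.038) lower. The 6 lists had an adjusted p of at least 0.887 with an estimated correlation. Of 100 splits of the libraries within subsets, 5 gave as many as 19 genes, with 161 in the highest other. All 5 kept both MPP4 1013/1013 libraries in their own group, while the 95 splits that did not gave at most 1 gene. The counts thus follow the contrast of those 2 libraries with the MPP4 wild-type libraries, and the splits that gave as many are just those that kept it, so their share cannot tell chance from an effect here.

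The genes near 0 in both MPP4 1013/1013 libraries were set against losses of transcripts in each library. Of 12463 genes with at least 1 CPM in wild-type MPP4, 668 had no counts in both. Independent loss at each library's own rate within bins of wild-type level would give 342. Losses in the 2 libraries were thus not independent. The odds ratio of 0 counts in both, over bins of wild-type level, was 6.44 (95% interval 5.53 to 7.5), within the 4.35 to 10.5 of the 3 pairs of +/1013 MPP4 libraries, so loss of the same genes as in other libraries remains a possible explanation. The 120 genes lower in 1013/1013 MPP4 had a median transcript length of 2124.25 bases, at percentile 100 of 10000 random gene sets matched on wild-type level (1341.5, with 95% of sets at 1064 to 1643), which is consistent with a poorer yield of long transcripts. An offset for transcript length left 104 genes called, 94 of them among the 133, but a smooth correction cannot restore counts of 0; the genotype, which the design names, stays open and untested.

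The higher ribosomal and respiratory-chain lists in 1013/1013 were set against the number of genes detected. In the 24 wild-type and +/1013 libraries, centred per group, the mean level of these 3 lists fell as the number of detected genes rose (Spearman rho = -0.681, p = 0.0066; Pearson r = -0.723, p = 0.00886, and -0.543 without the 2 libraries farthest from the median). Without the 6 of them numbered in multiples of 3, rho was -0.725 (p = 0.044) and r -0.756 (p = 0.0414, n = 18). A lower number of detected genes may therefore account for part of this pattern. In MPP1 the 1013/1013 libraries kept as many genes as wild type after thinning. There the mitochondrial ribosome and nuclear-encoded respiratory-chain lists were called lower at the preset correlation. Removing a smooth trend with transcript length left the median of the cytosolic ribosome list at 0.39, from 0.41. Such a trend was thus not the whole cause for that list. The mitochondrial ribosome and nuclear-encoded respiratory-chain lists kept medians of 0.29 and 0.28. How well the trend was fitted for the shortest genes was not checked, so a part played by length is not excluded. Of 100 splits, 40 called as many as the 10 lists of 1013/1013 against wild type, with a highest other count of 22, so chance is not excluded, and the genotype itself was not tested apart from these.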

How the results depend on the processing

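Of the alternatives below, the term for the 8 libraries numbered in multiples of 3, the fits without them, the fits without the 2 libraries of fewest genes and the term for the 11 libraries under 1 CPM of Ddx3y were tests chosen only after the data had been seen. Of planted 2-fold changes in 1013/1013 MPP4, 1.49% were recovered. Same-numbered libraries were not paired. Deviations from the group means correlated by a mean of 0.0447 over 160 same-numbered pairs, 46 of them over 0.1. Over 308 others the mean was -0.0229, with 21 over 0.1. These pairs include different genotypes, which cannot share animals. Within a genotype, across subsets, the mean was 0.061 over 48 same-numbered pairs (15 over 0.1). It was -0.0342 over 84 others (7 over 0.1). The voom block correlation was 0.0593. The 28 pairs of libraries numbered in multiples of 3 had a mean of 0.123, with 17 over 0.1. In 1013/1013, Xist did not follow the numbers, as given below. Ddx3y was present in wild type 1 and under 1 CPM in wild type 2 and 3 of every subset, so same-numbered wild-type libraries may come from the same animals. The p-values of means over subsets, which treat the libraries as independent, would then be too small. RLE size factors kept all 85 called gene results named in the text, the term 84, DESeq2 all 83 that it tested, no filter 77, the replicate block 73, limma-voom and the Ddx3y term 67 each, the series term 66, the fits without the 8 libraries 63 and those without the 2 libraries 57. None of the called results reversed. For each change below, the cause was not tested.

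With DESeq2, +/1013 against wild type gave 117, 206, 198 and 117 genes in MPP1 to MPP4 and 202 over subsets. 1013/1013 gave 116, 1159, 277 and 2110, and 1896 over subsets; 1013/1013 against +/1013 gave 784, the MPP4 effects 121 (+/1013) and 872 (1013/1013), and wild-type MPP2, MPP3 and MPP4 against MPP1 271, 600 and 777. With limma-voom, the subset counts were 2, 1, 16 and 12 for +/1013 and 29, 40, 23 and 373 for 1013/1013, the MPP4 effects 8 and 57, and the wild-type counts 6, 180 and 465. Without the 8 libraries, 1013/1013 gave 0 genes in MPP1, 1001 in MPP2, 64 in MPP4 and 1187 over subsets, 648 against +/1013, 33 for the MPP4 effect, and Cxcr4 passed at 1.37; +/1013 gave 15 lists. Without the 8 libraries, MPP2 and MPP4 each have a lone 1013/1013 library. The 1013/1013 counts outside MPP1 and the Cxcr4 call of that fit rest in part on these. With the term, 1013/1013 over subsets gave 207 genes and +/1013 gave 13 lists. Without the 2 libraries of fewest genes, 1013/1013 gave 20 genes in MPP2, 40 in MPP4 and 27 against +/1013.

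With the Ddx3y term, 1013/1013 gave 5 genes in MPP2 and +/1013 gave 16 lists, and Cxcr4 was 1.70 (adjusted p = 0.0615). With a replicate block, 1013/1013 MPP2 gave 3 genes, wild-type MPP2 1 and +/1013 13 lists. With the series term, 1013/1013 gave 76 genes in MPP4 and 85 over subsets, and wild-type MPP3 12. In fits of 1 subset alone, which have fewer samples, 1013/1013 gave 0 genes in MPP2 and 0 in MPP4. Without a filter, wild-type MPP2 gave 1. With an estimated correlation, 0 and 0 lists passed for +/1013 and 1013/1013, and with fry 1 and 4.

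Leaving out 1 library at a time gave these ranges. For +/1013: 0 to 1 in MPP2, 0 to 1 in MPP3, 4 to 5 over subsets, and 5 to 14 lists. For 1013/1013: 0 to 0 in MPP1, 1 to 1048 in MPP2, 0 to 13 in MPP3, 18 to 752 in MPP4, 37 to 1493 over subsets, 4 to 545 against +/1013, 9 to 453 for the MPP4 effect, 6 to 13 lists, and 0.81 to 1.30 for Cxcr4. In wild type: 0 to 2 in MPP2, 0 to 16 in MPP3 and 73 to 108 in MPP4.

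Of the single-gene results, the direction reversed only for values that never passed. Lists were less stable: in wild type against MPP1, without the 8 libraries, the medians of called lists turned from 5.34 to -0.85 in MPP2, 5.70 to -0.35 in MPP3 and 5.83 to -0.46 in MPP4 for mature neutrophil genes, and from 0.27 to -0.19 in MPP2 for cytosolic ribosome genes. In MPP4 the median of mitochondrially encoded respiratory-chain genes turned negative as well (-0.13). The Cxcr4 MPP4 effect of +/1013 was 0.17 with the block, 0.15 with the term, 0.66 without the 8 libraries and 0.43 with limma-voom (-0.62 to 1.23 leaving out 1 library), and that of 1013/1013 was 0.15 with the block, 0.14 with the Ddx3y term, 0.15 without the 8 libraries and 0.39 with limma-voom (-0.75 to 1.16). Cxcr4 in wild-type MPP3 against MPP1 was -0.01, -0.23, -0.03, -0.46 and -0.08 with the block, the term, the Ddx3y term, without the 8 libraries and with limma-voom (-0.45 to 0.79), and in MPP4 -0.03 without the 8 libraries (-0.03 to 1.72). Leaving out 1 library, Cxcr4 also reversed in +/1013 MPP3 (-0.37 to 1.41), 1013/1013 MPP3 (-0.09 to 1.15) and +/1013 MPP4 (-0.22 to 1.63), as did the +/1013 MPP4 effect of Aspa (-0.07 to 8.59); that of Cavin2 was 0.14 without the 8 libraries.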

Other observations

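Both tests of the genes near Cxcr4, the fits with a Ddx3y term and the splits that move same-numbered libraries together were chosen only after the result was seen; the tests on other splits of the samples were not.

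Of the 673 tested genes within 50 Mb of Cxcr4, 13 were called in 1013/1013 over the subsets, among them Dars, Stk25, Pam and Ctse. A chromosome segment from another strain, carried along with the targeted allele and differing in expression or in read mapping, is a candidate explanation: 10.2% of the genes called in 1013/1013 lay in this window against 3.6% of all tested genes (1-sided Fisher's exact test, p = 0.000728). Fewer detected genes in 1013/1013 would affect MPP1 little, where these libraries kept as many genes as the others. Of the 30 window genes called over MPP2 to MPP4, 21 moved the same way in MPP1. Their median was 0.27 (95% bootstrap interval 0.05 to 0.73), which leaves that explanation open for single genes. Fewer detected genes would not be expected to single out genes near Cxcr4. The window was chosen after called genes in it were seen, so 10.2% against 3.6% argues only weakly against that explanation for the excess. In the window 9 genes were higher and 4 lower, against 39 and 89 of all 128. An effect of the receptor on these genes, the difference the design names, stays open as well.

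Chance was tested by other splits of the libraries. For the 4 genes of +/1013 over subsets, 1 of 100 drawn splits gave as many, the real one, and the highest other gave 3. If the libraries are separate, that share is under 0.05. Splits outside the draw, given below, gave 12 and 35 genes, so chance is not excluded. For the 128 of 1013/1013 over subsets the share was also 1 of 100. The highest other split there called 123 genes, with 6 of the 8 1013/1013 libraries in their own group. It was among the 5 splits, with the real one, that kept both MPP4 1013/1013 libraries in their own group. The other 95 called at most 5 genes. A count near 128 thus arose only with those 2 libraries in their own group, in too few splits to exclude chance. The splits were not refitted under the alternatives, some of which called fewer than 123 genes in the real split (96 with the replicate block, 85 with the series term). In 1013/1013, Xist did not follow the library numbers. It had 126, 0, 152 and 0 CPM in number 1 of MPP1 to MPP4, and 155, 63, 0.0337 and 0 in number 2. The same animals are therefore doubtful for this genotype. If same-numbered libraries still come from the same animals, only 10 splits that move them together remain, too few for a share under 0.05. The real 128 then stood against a highest other count of 3. For +/1013, 3 of the 10 splits gave at least 4 genes: the real one and those with 35 and 12. The split with 35 set wild type 1 and +/1013 1 and 2 against wild type 2 and 3 and +/1013 3. It follows Ddx3y except in MPP1 +/1013 3 (42.6 CPM) and points to a structure of the samples. The split with 12 set wild type 1 and 2 and +/1013 2 against the rest, which does not follow Ddx3y. With the Ddx3y term the real split gave 4. Chance is not excluded for the 8 lists of +/1013 (62 of 100; highest other 21) or the 8 genes of 1013/1013 against +/1013 (9 of 100; highest other 29). Every split matches a count of 0, so the 100 of 100 for the +/1013 MPP4 effect (highest other 2) say nothing about chance. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. There, +/1013 gave 0 genes in each subset, with highest other counts of 0, 2, 1 and 1 in MPP1 to MPP4, and wild-type MPP2, MPP3 and MPP4 gave 0, 19 and 142 against MPP1, with a highest other count of 0 for each.

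All 4 genes called in +/1013 over subsets were also among the 39 called higher in 1013/1013. If the lists were independent, 0.0084 shared calls would be expected. All but Gm5874 lie within 50 Mb of Cxcr4. Both comparisons use the same wild-type libraries, so part of this overlap can come from them. The 20 simulations with shared controls and no effect gave 0 shared calls, but they called at most 1 gene in either comparison, so they do not measure that part.

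Some single-library values stood apart. Malat1, an abundant nuclear RNA, had 9.03 CPM in MPP4 1013/1013 2 and 107 in MPP4 1013/1013 1, against at least 80.7 in every library but the first of these. Xist, expressed from the inactive X chromosome, had 0 CPM in MPP2 1013/1013 1 and both MPP4 1013/1013 libraries, and 0.0337 in MPP3 1013/1013 2. Wild-type libraries had at least 38.2 CPM of Xist and +/1013 libraries at least 35, so its absence was seen only in 1013/1013 libraries. It was not seen in all of them: the other 1013/1013 libraries had 63 to 155 CPM. Those at or near 0 CPM of Xist had 9.83 to 44.6 CPM of Ddx3y. The Y-linked Ddx3y was under 1 CPM in 11 libraries, wild type 2 and 3 of every subset and +/1013 3 of MPP2, MPP3 and MPP4. Wild type 1 of MPP1 had 38.2 CPM of Xist and 49.2 of Ddx3y. The sex of the pools thus differed within groups and also between compared groups: in MPP4, wild type 2 and 3 had 133 and 351 CPM of Xist, and 1013/1013 1 and 2 had 44.6 and 14.1 CPM of Ddx3y. When a term for the 11 libraries was added, 1013/1013 against wild type gave 89 genes in MPP4, 79 of them among the 133, and 138 over subsets, 64 of them among the 128. That term marks libraries without Ddx3y and does not model the absence of Xist in 1013/1013 libraries. Sex may therefore account for some of the calls, and the genotype stays open.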
